A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

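The analysis used only processed data deposited for the series, with 6 single-colour oligonucleotide arrays of total RNA from budding yeast, W303-1a background. The arrays were 2 of wild type, 2 of a gpr1 deletion and 2 of a gpa2 deletion, grouped by the sample labels. Replicate numbers came from the sample titles. The source label of gpa2 array 2 marks a second experiment, and whether arrays with the same number were prepared together is not given in the sources used here. Each array gave 1 intensity per probe set, which per the labels is the signal deposited by the authors on a linear scale. The summary method and any scaling by the authors are not given in the sources used here. All columns were mapped to samples, with 0 left over.

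Median deposited intensities spanned 2.50-fold between arrays, with a largest gap of 1.32 on the log2 scale. A limit of 0.2 on that gap had been set before the data were examined, together with the comparisons, tests, gene lists, named genes and alternatives. The arrays were therefore quantile normalised. Values below the pooled 10th percentile, an intensity of 8.94 (log2 3.16), were then raised to it, and log2 was taken. The written plan lists the floor before the scaling, and here the scaling came first. Of 9335 probe sets, 60 were controls, and 2319 of the other 9275 were left out because their mean lay under the 25th percentile, which left 6956. Among those tested, 5650 name 1 gene, 275 several and 1031 none. Gene symbols were matched by gene identifier for 6504 probe sets, and 0 symbols had to be updated. Chromosome neighbours were taken from the gene order of the R64 assembly. Precision is limited by 2 arrays per group. The median standard error of a log2 change against wild type was 0.280, and dim probe sets near the floor give compressed changes.

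Changes were tested with limma 3.58.1 in R 4.3.3, with 1 coefficient per group over all 6 arrays, 3 residual degrees of freedom, moderation with a trend (5.52 prior degrees of freedom) and Benjamini-Hochberg adjustment at 0.05. The comparisons were each deletion against wild type, the deletions against each other, and their mean against wild type. The 31 gene lists were tested with camera at a preset correlation of 0.01, on 1 probe set per gene, where at least 5 members were measured, which left 29. Camera with an estimated correlation and fry were run beside it. Members were counted past the threshold over all probe sets and adjusted over the list alone. The likeness of the deletions was compared with 100 draws of simulated unchanged groups that share simulated wild-type arrays.

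Genes were named by a fixed rule. It takes GPR1 and GPA2, and for each deletion against wild type and the deletions against each other the 10 largest rises and 10 largest falls among probe sets past the threshold that name 1 gene. Where fewer passed, the list was filled to 10 by the smallest unadjusted p among genes whose arrays do not overlap. Up to 4 members of each gene list were added. Genes outside the rule are given as chosen after their values were seen.

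The procedure was tested on simulated data, in 10 rounds with 200 changed probe sets in each deletion. A 2-fold change was called for 36.3% of changed probe sets in the gpr1 comparison, 37.1% in the gpa2 comparison and 46.0% between the deletions, and a 4-fold change for 93.6%, 95.4% and 96.7%. The false share of calls was 6.87%, 7.91% and 5.93%, above the 5% aimed at. Between the deletions the changes of both counted, on average 187 of 2-fold and 192.4 of 4-fold, so its rates are not comparable with the others. A shifted list of 40 genes was called in 10 of 10 rounds, and 0 of 290 random lists were called. The simulated noise was independent between probe sets, so these rounds do not test list calls where members vary together.

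Alternatives were a replicate block, the values as deposited, median centring, other floors, other filters, other moderation, only the groups compared, other thresholds, and leaving out each array in turn. Groups of 2 arrays leave no test by regrouping samples. No raw data were used.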

Results

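Transcript levels were measured on 6 single-colour oligonucleotide arrays in budding yeast of the W303-1a strain, a common laboratory background. The samples were 2 of wild type, 2 of a strain with GPR1 deleted and 2 of a strain with GPA2 deleted. GPR1 encodes the G-protein-coupled receptor that senses glucose, and GPA2 encodes the alpha subunit of the G protein that acts with it in the cAMP and protein kinase A pathway. The study's title places both in the control of cell size by glucose. Their number limits the precision of every comparison. Each array held 9335 probe sets, of which 6956 were tested. The median deposited intensity was 562.9 and 373.6 on wild-type arrays 1 and 2, 525.9 and 265.4 on the gpr1 arrays, and 225.1 and 237.6 on the gpa2 arrays. After scaling, Pearson's r between the 2 arrays of a group, across probe sets, was 0.939 in wild type, 0.969 in the gpr1 deletion and 0.969 in the gpa2 deletion. Between arrays of different groups it ranged from 0.923 to 0.978, so arrays of a group were not always the most alike. The highest value joined gpa2 array 2 and gpr1 array 2. Wild-type array 1 was closer to gpr1 array 1 (0.964) than to wild-type array 2. The labels do not say that arrays of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

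The deleted genes were examined first, since they check the labels. GPR1 had deposited intensities of 5.1 and 2.8 on the gpr1 arrays, against 1086.4 and 1013.9 in wild type and 490.7 and 634.9 in the gpa2 deletion. It lay at the floor of the scale on both gpr1 arrays and was at least 91.9-fold lower than in wild type (log2 change -6.52 ± 0.32, SE, n = 2 arrays per group; limma adjusted p = 3.88e-05). This bound follows the floor: with the floor at the 25th percentile the log2 change was -3.46. GPA2 had deposited intensities of 9.3 and 10.9 on the gpa2 arrays, against 2410.3 and 1900.3 in wild type and 1619.3 and 1029.2 in the gpr1 deletion. Its log2 change in the gpa2 deletion was -6.57 ± 0.30 (limma adjusted p = 2.15e-05). Readings this low lie near background, so the size of this fall is uncertain: it was -4.47 with the floor at the 25th percentile and -7.73 on the values as deposited. Neither gene passed the test in the other deletion. The log2 change of GPA2 in the gpr1 deletion was -0.39 (adjusted p = 0.925), and that of GPR1 in the gpa2 deletion was 0.12 (adjusted p = 0.920). The sign of the latter depended on the processing, as it was -0.91 on the values as deposited, -0.08 and 0.33 without wild-type array 1 or 2, and 0.23 and 0.02 without gpa2 array 1 or 2. GPA2 in the gpr1 deletion was -0.23 and -0.55 without gpr1 array 1 or 2, and -0.73 on the values as deposited.

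**Figure D1:**
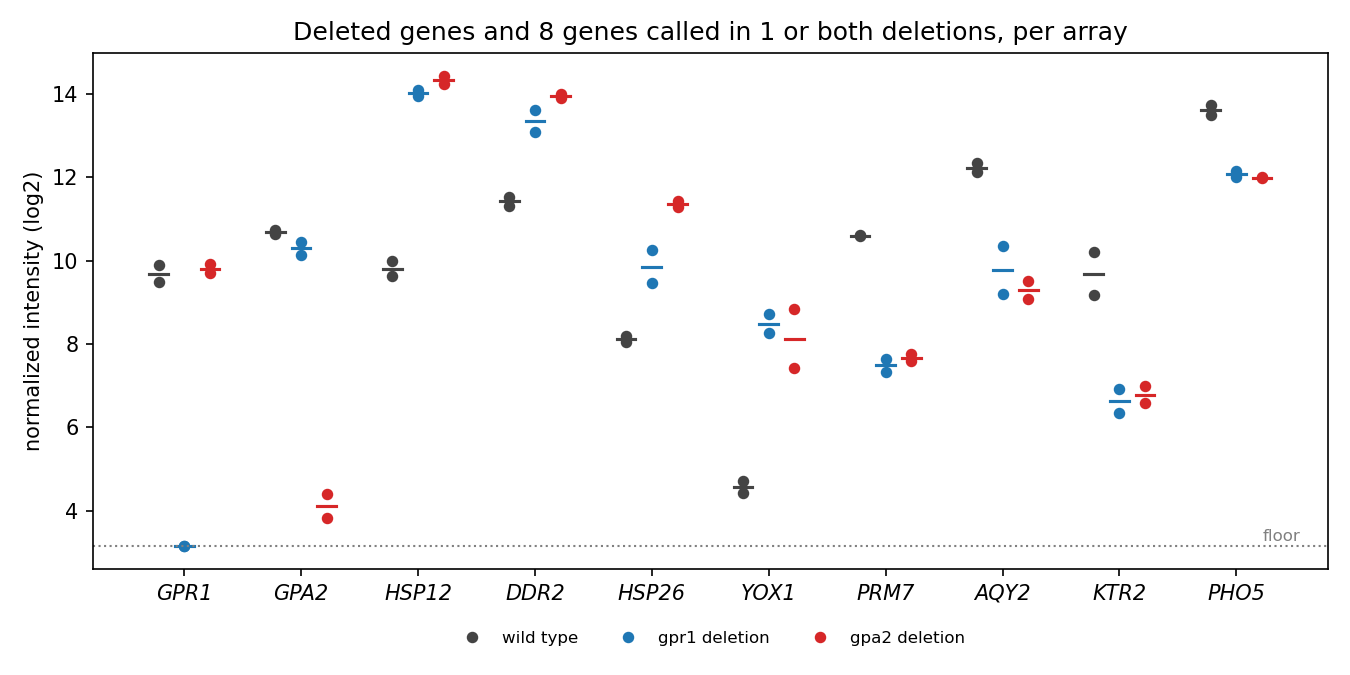
Normalised log2 intensity (vertical axis) of GPR1, GPA2, HSP12, DDR2, HSP26, YOX1, PRM7, AQY2, KTR2 and PHO5 on each of the 6 arrays, with 1 point per array, a bar at each group mean and a dotted line at the floor of 3.16; levels of different genes are not comparable. GPR1 lies at the floor on both gpr1 arrays, and HSP12 has means of 14.03 and 14.34 in the gpr1 and gpa2 deletions against 9.81 in wild type. In the main fit HSP26 passed the test against wild type in the gpa2 deletion alone, and with the replicate number as a block it passed in the gpr1 deletion too.

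In the gpr1 deletion, the genes with the largest rise against wild type included stress genes. HSP12, which encodes a small membrane-associated stress protein, rose 18.6-fold (log2 change 4.22 ± 0.21, SE, n = 2 arrays per group; limma adjusted p = 3.88e-05), from a mean log2 intensity of 9.81 to 14.03. DDR2, another stress-induced gene, rose 3.81-fold (1.93 ± 0.23, adjusted p = 0.0186). YOX1, a homeodomain repressor of genes of the early cell cycle, rose 15.2-fold (3.93 ± 0.50, adjusted p = 0.0284; log2 change 2.27 with the floor at the 25th percentile). AQR1, a plasma membrane transporter (log2 change 2.00), and ECM13 (1.79) rose as well, with adjusted p of 0.0475 and 0.0459.

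Among genes that fell in the gpr1 deletion, PRM7, known as pheromone-regulated, dropped 8.69-fold (log2 change -3.12 ± 0.25, adjusted p = 0.00174), and its other probe set read -2.18. KTR2, a mannosyltransferase of the Golgi (-3.05, adjusted p = 0.0418), AQY2, an aquaporin (-2.46, adjusted p = 0.0475), and PHO5, the secreted acid phosphatase (-1.55, adjusted p = 0.0252), fell too. So did YJR115W (-3.56, adjusted p = 0.0497), YOR385W (-1.54, adjusted p = 0.0459) and FKS1, a subunit of glucan synthase (-1.59, adjusted p = 0.0475). The FKS1 call came from 2837_s_at, a probe set that may share sequence with other genes, while the brightest FKS1 probe set, 9966_at, read -0.20. Of the others, 2835_at (-1.29), 2836_g_at (-0.99) and 2838_s_at (-0.95) read lower without passing, and 2839_s_at (-0.14), 2840_s_at (-0.02) and 2841_s_at (-0.14) read near 0. In the R64 assembly PRM7 lies 3 genes and BSC1 2 genes from the deleted GPR1. PUS9, the gene between BSC1 and GPR1, read -0.45 in the gpr1 and -0.38 in the gpa2 deletion. BSC1, next to PRM7, stayed outside the test because its mean over all arrays was dim. Its deposited intensity was 897.7 and 708.7 in wild type and at most 6.2 on the 4 mutant arrays, all at the floor, so that it was at least 71.1-fold lower in each deletion. It was chosen after its values were seen. A probe set with no gene name, 3982_at, lay at the floor on both wild-type arrays and was at least 1767-fold higher in the gpr1 deletion (adjusted p = 1.49e-06), and another, 5500_at, fell (-2.53, adjusted p = 0.0166). By its number 3982_at stands between probe sets of SCEI and COX2, both mitochondrially encoded. Which transcript it reads was not tested.

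In all, 16 of 6956 probe sets passed in the gpr1 deletion against wild type, 6 higher and 10 lower, and 462 had an unadjusted p under 0.05. Chance alone gives 347.8 if all groups vary alike, and the wild-type arrays varied more than those of the mutants. Genes named by rank whose change did not pass were FMP33 (log2 change 3.24, adjusted p = 0.0594), PIB1 (2.42, 0.0536), HSP26 (1.73, 0.0730), NCA3 (1.55, 0.0536), ALD4 (1.17, 0.0871), YDL241W (-3.94, 0.0639; -4.81 and -3.08 without gpr1 array 1 or 2) and YLL053C (-2.09, 0.0639). With the floor at the 25th percentile FMP33 read 2.05, and with the replicate number as a block FMP33 and HSP26 passed. The count was 5 without gpr1 array 2, 7 without gpr1 array 1, 8 without either gpa2 array, 53 without wild-type array 1 and 31 without wild-type array 2. GPR1, HSP12, PRM7 and 3982_at passed without any 1 array, the other named calls lost theirs without at least 1, and on the values as deposited 15 probe sets passed higher and 9 lower.

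By gene list, the general stress genes under the transcription factors Msn2 and Msn4 lay above wild type in the gpr1 deletion. Their median log2 change was 0.33, 45 of 54 measured members were positive, and HSP12 and DDR2 rose; 11 members rose when adjusted over the list alone (camera adjusted p = 2.17e-12; adjusted p = 0.319 with an estimated correlation). Trehalose and glycogen genes, which share 11 members with the stress list, had a median of 0.24 with 15 of 19 positive. None of them passed over all probe sets by limma (4 higher at an unadjusted p under 0.05), 3 rose when adjusted over the list alone, and TSL1 read 1.11 ± 0.24 (camera adjusted p = 0.00191; adjusted p = 0.347 with an estimated correlation). Genes repressed by glucose had a median of 0.30 with 16 of 22 positive, among them ALD4 at 1.17 and CYB2 at 0.94. None passed over all probe sets by limma (6 higher and 1 lower at an unadjusted p under 0.05), and 4 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.00304; adjusted p = 0.347 with an estimated correlation). Without wild-type array 1 neither the trehalose list (adjusted p = 0.0787) nor the glucose-repressed list (0.186) passed, and without the filter on dim probe sets the latter had 0.0583. The trehalose median was 0.39 without gpr1 array 1 and 0.08 without gpr1 array 2.

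Genes of oxidative phosphorylation had a median of 0.27 in the gpr1 deletion, with 34 of 36 positive, such as QCR2 (0.62 ± 0.24) and ATP14 (0.50 ± 0.18). None passed by limma over all probe sets or over the list alone, and 5 were higher at an unadjusted p under 0.05 (camera adjusted p = 1.95e-07; adjusted p = 0.205 with an estimated correlation). The citric acid cycle list had a median of 0.22 with 17 of 19 positive, including SDH3 at 0.59 and SDH2 at 0.58, and again none passed (3 higher at an unadjusted p under 0.05; camera adjusted p = 0.00304; adjusted p = 0.541 with an estimated correlation). Beside these lists stands a difference between the wild-type arrays. OLI1, a mitochondrially encoded ATP synthase subunit, had deposited intensities of 7954.7 and 5.6 on wild-type arrays 1 and 2, against 2585.7, 1475.1, 7768.6 and 3247.6 on the 4 mutant arrays, and the brightest probe set of COX1, a cytochrome oxidase subunit, read 931.8 and 12.5 in wild type. Another, dimmer probe set of COX1 read 86.9 and 46.3, which is a normalised difference of 0.05. These genes were chosen after their values were seen. The ratio of the 3' to the 5' control of SPT15, a sign of RNA quality, was 10.3 on wild-type array 2 and 3.16 to 4.83 on the other 5 arrays. That of ACT1 was 1.26 and 1.29 on wild-type arrays 1 and 2 and higher, 1.35 to 1.54, on the 4 mutant arrays. Whether RNA quality bears on the comparisons with wild type was not tested. Without wild-type array 2 the medians were 0.23 for oxidative phosphorylation and 0.35 for the citric acid cycle, both past the threshold. The citric acid cycle list did not pass without wild-type array 1 (median 0.06, adjusted p = 0.357) or without gpr1 array 2 (0.13, adjusted p = 0.0883).

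Amino acid biosynthesis genes lay below wild type in the gpr1 deletion, with a median of -0.28 and 41 of 52 negative. HIS4 read -1.14 and HIS6 -0.73, and none passed by limma (6 lower at an unadjusted p under 0.05; camera adjusted p = 9.50e-06; adjusted p = 0.319 with an estimated correlation). Genes of the phosphate response had a median of -0.31 with 11 of 16 negative, of which PHO5 fell and PHO89, a phosphate transporter, read -1.58 (camera adjusted p = 0.00191; adjusted p = 0.347 with an estimated correlation); 2 fell when adjusted over the list alone. Ribosome biogenesis genes had a median of -0.17 with 66 of 90 negative and none passing by limma (1 lower at an unadjusted p under 0.05; camera adjusted p = 0.00304; adjusted p = 0.541 with an estimated correlation). That list did not pass without wild-type array 1 (adjusted p = 0.178) or without gpr1 array 2 (median -0.08, adjusted p = 0.355), and its median was -0.27 without gpr1 array 1. Its mean log2 intensity was 10.53 on gpr1 array 1, where the median deposited intensity was 525.9, and 10.32 on gpr1 array 2, where it was 265.4. The amino acid median was -0.14 without wild-type array 2.

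Lists of the cell cycle and of metals made up the rest of the 12 that camera called in the gpr1 deletion. Genes transcribed at G1/S had a median of 0.25 with 25 of 31 positive and YOX1 alone passing (camera adjusted p = 0.000606; adjusted p = 0.347 with an estimated correlation). The list of G1 cyclins and size regulators, which bears on the size question of the study, had a median of 0.16 with 17 of 22 positive and none passing by limma (3 higher at an unadjusted p under 0.05; camera adjusted p = 0.00630; adjusted p = 0.551 with an estimated correlation). PCL1 read 1.32 ± 0.34, PCL2 0.87, FAR1 0.61, CLN1 0.58, CLN3 0.10 and WHI5 0.08. Mitotic and M/G1 genes had a median of 0.17 (21 of 33 positive) and iron and copper genes one of 0.22 (20 of 31 positive), with camera adjusted p of 0.0188 and 0.0321. With an estimated correlation the adjusted p was 0.541 and 0.347, and by limma none of either list passed (3 and 4 higher at an unadjusted p under 0.05). Without wild-type array 1 none of these 4 lists passed (medians 0.09, 0.04, 0.06 and 0.04 in the order given), without gpr1 array 1 the mitotic (0.04) and metal (0.14) lists did not, and without gpr1 array 2 the size list did not (adjusted p = 0.104) while the mitotic median was 0.10. The size median was 0.29 without wild-type array 2 and 0.27 without gpr1 array 1. The median of all probe sets shifts by -0.32 on the values as deposited, where 7 of the 12 lists passed, and the list medians of -0.08 to -0.16 there for glucose-repressed, size, mitotic, citric acid cycle and metal genes did not.

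In the gpa2 deletion, HSP12 rose 23.1-fold against wild type (log2 change 4.53 ± 0.21, SE, n = 2 arrays per group; limma adjusted p = 2.15e-05). HSP26, a small heat shock chaperone, rose 9.45-fold (3.24 ± 0.29, adjusted p = 0.00213), and DDR2 rose 5.82-fold (2.54 ± 0.23, adjusted p = 0.00213). GPH1, glycogen phosphorylase (3.19), PUT4, the proline permease (3.12), MPC3, a subunit of the mitochondrial pyruvate carrier (2.75), FMP33 (3.47) and FMP45 (2.47) rose with adjusted p between 0.0150 and 0.0456. CCW12, a cell wall mannoprotein, rose 12.6-fold (3.66 ± 0.61, adjusted p = 0.0444), and YOX1 rose 11.8-fold (3.56 ± 0.50, adjusted p = 0.0265). The size of these rises depended on single arrays. Without gpa2 array 1 or 2, CCW12 read 2.99 and 4.33 and YOX1 2.85 and 4.27. Without wild-type array 1 or 2, PUT4 read 4.09 and 2.15. With the floor at the 25th percentile YOX1 read 1.90, FMP33 2.28 and MPC3 1.48.

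Genes that fell in the gpa2 deletion included YDL241W (log2 change -4.97 ± 0.63, adjusted p = 0.0162; -4.35 and -5.60 without gpa2 array 1 or 2, -3.75 with the floor at the 25th percentile), YJR115W (-3.25, adjusted p = 0.0406; -2.55 and -3.95 without gpa2 array 1 or 2), AQY2 (-2.94, adjusted p = 0.0150), PRM7 (-2.93, adjusted p = 0.00213) and KTR2 (-2.91, adjusted p = 0.0285). SSK1, a response regulator of the osmotic stress pathway, fell by 3.06 (adjusted p = 0.0371) and EAF7, a subunit of the NuA4 histone acetyltransferase, by 2.29 (adjusted p = 0.0322). YLL053C, the chromosome neighbour of AQY2 in the R64 assembly, read -2.37 (adjusted p = 0.0265), and PBY1 passed narrowly (-2.44, adjusted p = 0.049997; -1.45 with the floor at the 25th percentile). The unnamed probe set 3982_at was at least 1539-fold higher than in wild type (adjusted p = 1.74e-06), and 11262_s_at, a probe set that names several genes, fell (-1.60, adjusted p = 0.0214).

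In all, 54 of 6956 probe sets passed in the gpa2 deletion, 33 higher and 21 lower, and 796 had an unadjusted p under 0.05. The count was 7 without gpa2 array 1, 10 without gpa2 array 2, 29 without gpr1 array 1, 30 without gpr1 array 2, 179 without wild-type array 1 and 70 without wild-type array 2. On the values as deposited, where the median of all probe sets lay at -1.02, 19 passed higher and 107 lower, of which 30 were among the 54. GPA2, HSP12, HSP26, DDR2, PRM7 and 3982_at passed without any 1 array, and the other named calls lost theirs without at least 1. Without the filter on dim probe sets 15 passed.

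The stress list stood highest in the gpa2 deletion, with a median of 0.70 and 49 of 54 members positive. Its mean log2 intensity was 9.64 and 9.62 on wild-type arrays 1 and 2, 10.06 and 10.27 on the gpr1 arrays, and 10.57 and 10.64 on the gpa2 arrays, the dimmest. HSP12, HSP26, DDR2, GPH1, RTN2 (2.20), MSC1 (2.18), GAD1 (1.96), PGM2 (1.88), TFS1 (1.86), TSL1 (1.49) and OM14 (1.28) rose, and adjusted over the list alone 22 rose and 1, the protease gene PRB1 (-0.64), fell (camera adjusted p = 8.42e-24; adjusted p = 0.159 with an estimated correlation). Trehalose and glycogen genes had a median of 0.52 with 17 of 19 positive, of which PGM2, GPH1 and TSL1, all also on the stress list, rose; adjusted over the list alone 6 rose (camera adjusted p = 3.88e-08; adjusted p = 0.251 with an estimated correlation). Ribosome biogenesis genes had a median of -0.39 with 81 of 90 negative. The mean log2 intensity of this list nearly followed array brightness. It was 10.61 and 10.54 on wild-type arrays 1 and 2, 10.53 and 10.32 on the gpr1 arrays, and 10.17 and 10.19 on the gpa2 arrays, the dimmest. None passed by limma over all probe sets or over the list alone, 19 were lower at an unadjusted p under 0.05, and RPA190, the largest subunit of RNA polymerase I, read -1.54 ± 0.29 on its brightest probe set and -0.67 to 0.07 on the 5 others (camera adjusted p = 1.26e-10; adjusted p = 0.308 with an estimated correlation).

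Respiratory genes lay above wild type in the gpa2 deletion as well. Oxidative phosphorylation had a median of 0.26 with 33 of 36 positive and none passing by limma (6 higher at an unadjusted p under 0.05; camera adjusted p = 8.56e-06; adjusted p = 0.159 with an estimated correlation), with QCR2 at 0.79 and COX5B at 1.12. The citric acid cycle had a median of 0.35 with 17 of 19 positive, SDH2 at 0.76 and none passing (3 higher at an unadjusted p under 0.05; camera adjusted p = 0.000657; adjusted p = 0.430 with an estimated correlation). Both passed without wild-type array 2, the array low in OLI1 and in the brightest COX1 probe set, with the SPT15 ratio of 10.3 (medians 0.28 and 0.46), and neither passed on the values as deposited (adjusted p = 0.279 and 0.405). Without wild-type array 1 the citric acid cycle list did not pass (median 0.16, adjusted p = 0.113). Of the glucose-repressed genes, ALD4, a mitochondrial aldehyde dehydrogenase (1.55, adjusted p = 0.0178), and CYB2, a lactate dehydrogenase (1.29, adjusted p = 0.0458), rose, and 16 of 22 were positive with a median of 0.33; adjusted over the list alone 4 rose and 1 fell (camera adjusted p = 0.00739; adjusted p = 0.408 with an estimated correlation). Without wild-type array 1 this list had an adjusted p of 0.147.

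Amino acid biosynthesis genes had a median of -0.32 in the gpa2 deletion with 42 of 52 negative, HIS4 at -1.30 and LEU1 at -0.73, and none passing by limma (8 lower at an unadjusted p under 0.05; camera adjusted p = 9.21e-06; adjusted p = 0.251 with an estimated correlation). In the phosphate list 14 of 16 members were negative with a median of -0.28, and PHO5 fell (-1.64, adjusted p = 0.0150); 2 fell when adjusted over the list alone (camera adjusted p = 0.000281; adjusted p = 0.321 with an estimated correlation). Genes transcribed at G1/S had a median of 0.14 with 22 of 31 positive and YOX1 passing (camera adjusted p = 0.0323; adjusted p = 0.480 with an estimated correlation). The size list had a median of 0.13 with 14 of 22 positive and was not called (camera adjusted p = 0.0670), and none of its members passed by limma (3 higher at an unadjusted p under 0.05), with PCL2 at 1.33, PCL1 at 1.21, SIC1 at 0.66, WHI5 at 0.37 and CLN3 at 0.17. A list drawn up beforehand as W303 marker genes, whose members were not checked against the strain's genotype, had a median of -0.34 with 6 of 7 negative. HIS3 read -1.13 (-0.35 on another probe set), URA3 -0.55 and LEU2 -0.29 (0.05 and -0.06 on 2 others). LYS2 read -0.39, ADE2 -0.34, CAN1 -0.25 and TRP1 0.09. None of these passed over all probe sets by limma (2 lower at an unadjusted p under 0.05) and HIS3 fell when adjusted over the list alone (camera adjusted p = 0.0250; adjusted p = 0.430 with an estimated correlation). The G1/S list did not pass without wild-type array 1 (median 0.05) or gpa2 array 2 (0.10), and read 0.24 without gpa2 array 1. The marker list did not pass without gpa2 array 2 (-0.40) or wild-type array 2 (-0.19), and read -0.67 without wild-type array 1. Neither list passed on the values as deposited (adjusted p = 0.294 and 0.119). The phosphate median was -0.46 without gpa2 array 2 and -0.45 without wild-type array 1, and the amino acid median -0.21 without wild-type array 2.

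**Figure D2:**
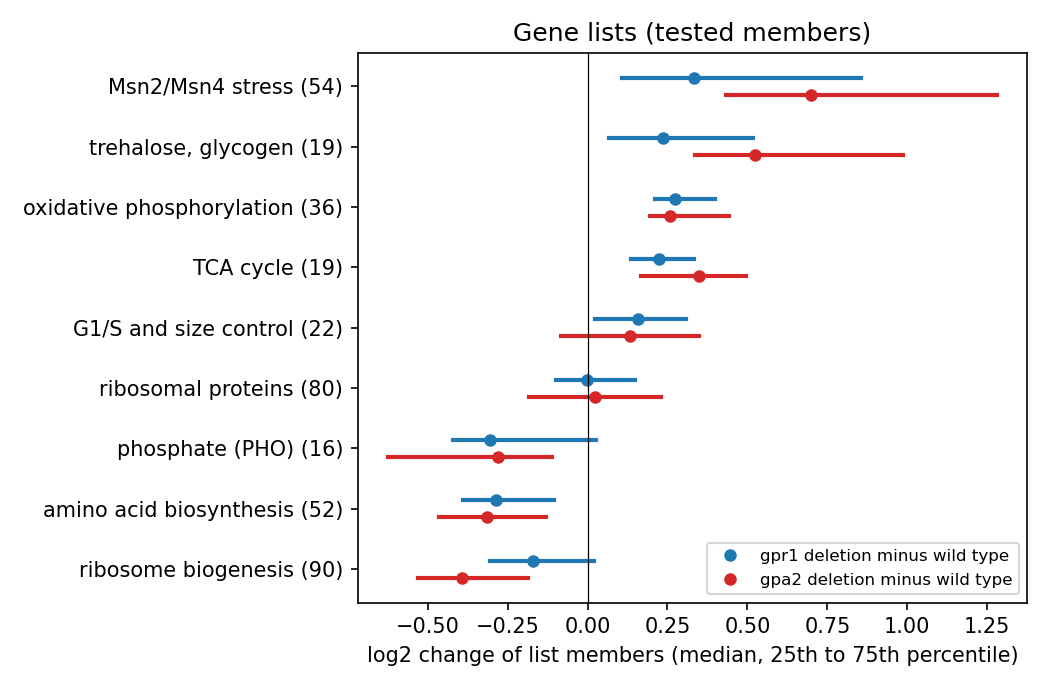
Median log2 change against wild type (horizontal axis) of 9 gene lists in the gpr1 deletion (blue) and the gpa2 deletion (red), with lines from the 25th to the 75th percentile of each list's members. The stress list has medians of 0.33 and 0.70 and ribosome biogenesis medians of -0.17 and -0.39; on the values as deposited the median of all probe sets lies at -0.32 and -1.02, which shifts every list.

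The deletions were then set against each other, which asks whether loss of the receptor and loss of the G protein subunit differ. GPR1 was at least 100.1-fold lower in the gpr1 deletion (log2 difference -6.65 ± 0.32, SE, n = 2 arrays per group; limma adjusted p = 4.60e-05; -3.59 with the floor at the 25th percentile). GPA2 was higher there (6.18 ± 0.30, limma adjusted p = 4.60e-05; 4.08 with the floor at the 25th percentile and 5.59 with a pseudocount). No other gene passed, and 163 of 6956 probe sets had an unadjusted p under 0.05, where chance gives 347.8. All comparisons use 1 estimate of spread, which includes the wild-type arrays. Those varied most, with a median SD of 0.270 against 0.175 and 0.196 in the gpr1 and gpa2 deletions. The estimate may be too large between the deletions and too small against wild type, so the low count does not measure their likeness. The nearest were ARI1 (-1.38 ± 0.20, adjusted p = 0.236), EAF7 (2.06 ± 0.34, adjusted p = 0.454), CCW12 (-3.30 ± 0.61, adjusted p = 0.618), HSP26 (-1.51 ± 0.29, adjusted p = 0.646) and SOL4 (-1.25 ± 0.26, adjusted p = 0.869), with negative values lower in the gpr1 deletion. CCW12 was -2.47 and -4.14 without gpr1 array 1 or 2, and -2.64 and -3.97 without gpa2 array 1 or 2. YNCK0003W, on a probe set that may share sequence with other genes, read 2.68, SNT309 2.24, PBY1 1.81, HIS3 1.22 (0.10 on another probe set) and SIT1 1.20, none past the threshold, and SNT309 was 1.49 and 2.98 without gpr1 array 1 or 2. With the floor at the 25th percentile YNCK0003W read 1.40, SNT309 1.09 and PBY1 0.82. The count was 5 without gpr1 array 2 and 10 on the values as deposited.

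Between the deletions, 3 lists were called. Stress genes were lower in the gpr1 than in the gpa2 deletion, with a median difference of -0.39 and 48 of 54 negative. None passed over all probe sets by limma (15 lower at an unadjusted p under 0.05), and HSP26 and SOL4 were lower when adjusted over the list alone (camera adjusted p = 5.96e-18; adjusted p = 0.406 with an estimated correlation). Trehalose and glycogen genes had a median difference of -0.39 with 18 of 19 negative and none passing by limma (3 lower at an unadjusted p under 0.05; camera adjusted p = 1.28e-07; adjusted p = 0.420 with an estimated correlation). Ribosome biogenesis genes had a median difference of 0.24 with 79 of 90 positive and none passing by limma (3 higher at an unadjusted p under 0.05; camera adjusted p = 3.47e-10; adjusted p = 0.541 with an estimated correlation). Its mean log2 intensity was 10.53 on gpr1 array 1, the brighter, and 10.32 on gpr1 array 2, against 10.17 and 10.19 on the dimmer gpa2 arrays. All 3 passed without any 1 of the 6 arrays, with a trehalose median of -0.21 without gpa2 array 2 and -0.26 without gpr1 array 1, and a ribosome biogenesis median of 0.14 without gpr1 array 1. On the values as deposited, where the median of all probe sets lay at 0.70, the stress and trehalose medians were 0.30 and 0.33, below that shift, and the calls held.

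The mean of both deletions was compared with wild type because the genes belong to 1 signalling system. HSP12 rose 20.7-fold (log2 change 4.37 ± 0.18, SE, n = 4 mutant and 2 wild-type arrays; limma adjusted p = 1.29e-05), PIB1, a ubiquitin ligase of the endosome and vacuole, rose (2.24, adjusted p = 0.0216), and RTA1 fell (-1.91, adjusted p = 0.0331). In all 55 probe sets passed, 34 higher and 21 lower, and 772 had an unadjusted p under 0.05. The count was 18 without either gpa2 array, 33 without gpr1 array 1, 17 without gpr1 array 2 and 142 without wild-type array 1, and on the values as deposited 17 passed higher and 46 lower. The probe sets past the threshold that name no gene or several were 3982_at, 10836_at (1.02), 11262_s_at (-1.45), 5500_at (-1.76) and 7003_at (-1.68). Camera called 11 lists in this mean, 0 of them with an estimated correlation, where 4 had an unadjusted p under 0.05; the lowest adjusted p there was 0.176.

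The deletions were compared across probe sets, with the wild-type arrays shared by both comparisons. In all, 12 probe sets passed in both, 5 higher and 7 lower. Independent lists of these sizes would share 0.0285 higher and 0.0302 lower ones, a value that leaves out the shared arrays. Unchanged groups simulated against shared wild-type arrays, themselves simulated, shared at most 1 higher and 2 lower ones in any of 100 draws, a value that leaves out any effect. HSP12, DDR2, YOX1, ECM13 and 3982_at were higher in both, and KTR2, AQY2, YJR115W, PHO5, YOR385W and both probe sets of PRM7 were lower. Across probe sets, which are not independent replicates, Pearson's r of the log2 changes was 0.774 and Spearman's rho 0.728, with 76.7% of the same sign. Unchanged groups simulated against shared wild-type arrays, themselves simulated, gave a mean r of 0.501 (maximum 0.546 of 100 draws) and 66.6% of the same sign. The covariance was 0.212 against 0.0612 simulated, a difference of 0.151. Both simulations gave all groups the same spread and drew the noise independently between probe sets. Noise shared between probe sets would widen the range of the draws, so their maximum is not a firm bound. The median SD between the 2 arrays of a group was 0.270 in wild type, 0.175 in the gpr1 and 0.196 in the gpa2 deletion. More variable shared arrays would raise the simulated agreement, so the excess over it may be overstated. With a separate wild-type array for each deletion, r was 0.231 or 0.191, depending on which array went to which deletion, and the covariance 0.0911 or 0.0788, so part of the excess may come from the shared controls. Without gpr1 array 2, r was 0.573.

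**Figure D3:**
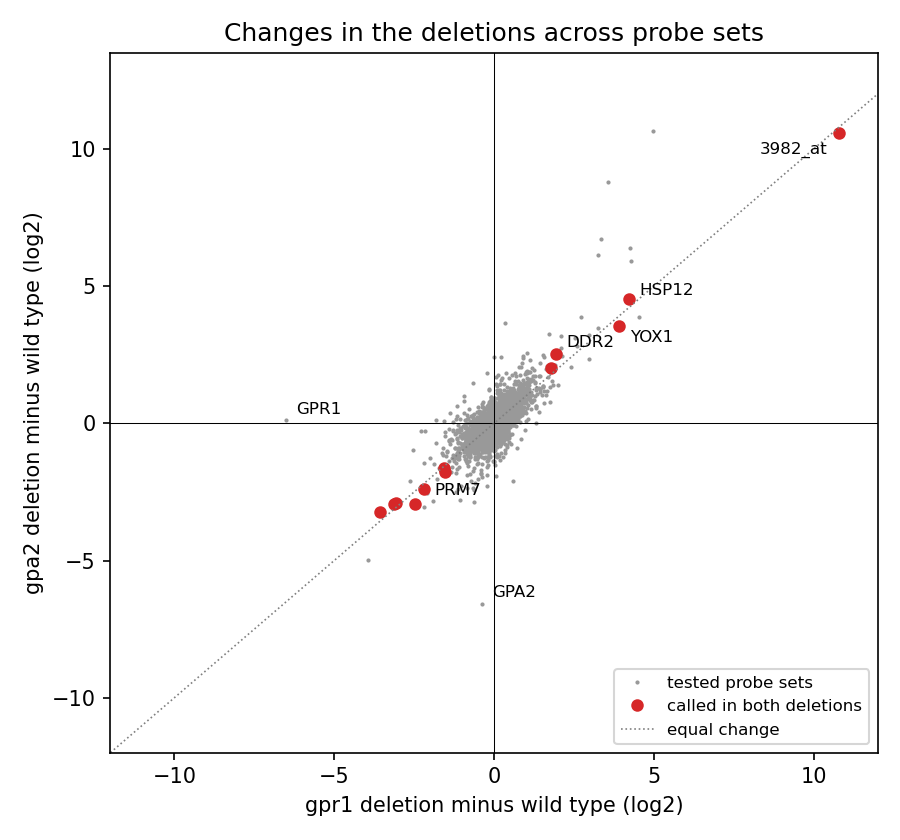
Log2 change against wild type in the gpr1 deletion (horizontal axis) and in the gpa2 deletion (vertical axis) for each of the 6956 probe sets, with the 12 called in both in red and a dotted line of equal change. Both axes share the wild-type arrays. The value of r is 0.774, against 0.501 on average for simulated unchanged groups. These were drawn independently between probe sets and with equal spread in all groups, although wild type varied more.

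Within the cAMP and protein kinase A pathway, only the deleted gene itself passed in either deletion. In the gpr1 deletion 13 of 23 measured members were positive with a median of 0.06, and in the gpa2 deletion 16 were positive with a median of 0.12 (camera adjusted p = 0.949 and 0.694). MSN2, a transcription factor of the stress response, read 0.63 and 0.72 in the gpr1 and gpa2 deletions, PDE2, the high-affinity cAMP phosphodiesterase, 0.42 and 0.39, and the kinase subunit gene TPK2 -0.11 and 0.39. The list's mean was -0.23 and -0.17 because it holds the deleted genes, so that median and mean differed in sign, and the sign of the test was down in the gpr1 and up in the gpa2 deletion. Hexose transport and glucose sensing genes had medians of 0.24 and 0.14 with 9 and 6 of 12 positive. None passed by limma in either deletion (1 higher and 1 lower, and 3 higher and 2 lower, at an unadjusted p under 0.05; camera adjusted p = 0.332 and 0.694), with HXT3, a low-affinity glucose transporter, at -0.51 and -0.70. Of the other W303 values, HIS3 in the gpr1 deletion was 0.09 (-0.25 on another probe set) and URA3 -0.37, and that marker list had a median of -0.19 with 5 of 7 negative and was not called (camera adjusted p = 0.327).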

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

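Of the tests in this part, those on array brightness and on glucose exhaustion, and the rule that found AIM33, were chosen after the result was seen.

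Differences between the deletions were tested directly. Ribosome biogenesis genes had a median difference, gpr1 minus gpa2 deletion, of 0.24, and general stress genes and trehalose and glycogen genes -0.39 each, by camera with a preset correlation; with an estimated correlation the adjusted p was 0.541, 0.406 and 0.420. The trehalose median was -0.21 without gpa2 array 2 and -0.26 without gpr1 array 1, and the ribosome biogenesis median 0.14 without gpr1 array 1. GPA2 (log2 difference 6.18) and GPR1 (-6.65) differ because each is the gene deleted in 1 of the strains.

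The stress difference was weighed further. The gpa2 arrays were the dimmest, so brightness may account for part of it. With array brightness as a covariate the median difference was 0.28 (SE 0.0671 over genes, 42 of 54 members positive), gpa2 minus gpr1, against 0.39 without it, which leaves brightness open. For the ribosome biogenesis list, whose mean log2 intensity nearly followed brightness (10.53 and 10.32 on the gpr1 arrays with median intensities of 525.9 and 265.4, and 10.17 and 10.19 on the gpa2 arrays with 225.1 and 237.6), brightness stays open as well. The covariate test was not run on the ribosome biogenesis list. For the stress list it replaced an earlier comparison, seen first. There the stress list mean on gpr1 array 2 lay at -0.302 against the lower gpa2 array, with 39 of 54 genes lower. The median intensity of gpr1 array 2 was 1.18 times that of gpa2 array 1 and 1.12 times that of gpa2 array 2. Of the genes chosen because they rise when glucose runs out, 5 were bright enough to test, ADH2, ICL1, PCK1, SUC2 and ACS1. Their median difference, gpa2 minus gpr1, was 0.0848 (SE 0.0990 over genes, not arrays), below the 0.39 of the stress list. That argues against exhaustion itself in the gpa2 cultures, for these genes. Glucose that was lower but not exhausted was not tested and stays open. A biological difference between loss of the receptor and of the G protein subunit stays open as a hypothesis.

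AIM33 gave a signal outside the tested probe sets. It was left out as dim, lay at the floor on both wild-type arrays, and had a mean log2 intensity of 7.16 on the 4 mutant arrays (7.88 and 6.74 in the gpa2 deletion, 7.30 and 6.74 in the gpr1 deletion), at least 16.0-fold higher. An earlier form of the rule that found it returned no gene, and no explanation was tested. Without the filter on dim probe sets AIM33 did not pass by limma. Other left-out probe sets did, among them BSC1 and ECM29 (log2 change -3.03 in the gpr1 and -2.89 in the gpa2 deletion).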

How the results depend on the processing

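All alternative settings in this part had been written down beforehand. The correlations of pair deviations and the principal components given below were not in that plan. Counts are given for the gpr1 deletion, the gpa2 deletion, the deletions against each other and their mean against wild type, where 16, 54, 2 and 55 probe sets passed. Where a count moved, the cause was not tested unless stated.

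With the replicate number as a block the counts were 33, 123, 2 and 131. Beyond the number, the labels say only that gpa2 array 2 belongs to a second experiment. The deviations of the pairs correlated at 0.21 (gpa2 with gpr1), 0.40 (gpa2 with wild type) and 0.20 (gpr1 with wild type). The second principal component (30.7%) had 1 sign on the arrays numbered 1 and the other on those numbered 2. With 2 arrays per group, deviations within a group mirror each other, so an arbitrary numbering can also give only positive correlations. Whether arrays of a number share a run is not settled by this, and the block changed no list call. On the values as deposited the counts were 24, 126, 10 and 63. Without the filter on dim probe sets they were 13, 15, 5 and 15. With a mean above the median of all probe sets 10 passed in the gpr1 deletion and 0 between the deletions by limma (85 at an unadjusted p under 0.05), where GPR1 and GPA2 were not tested. Moderation without a trend gave 6, 26, 2 and 29. Unmoderated statistics gave 0 in all 4 (436, 660, 211 and 636 at an unadjusted p under 0.05). With only the groups compared, 8 and 27 passed in the gpr1 and gpa2 deletions, and with an adjusted p under 0.1, 26, 109 and 102 passed in these and the mean.

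Leaving out each array in turn gave 5 (without gpr1 array 2) to 53 (without wild-type array 1) in the gpr1 deletion, 7 (without gpa2 array 1) to 179 (without wild-type array 1) in the gpa2 deletion, 2 to 5 (without gpr1 array 2) between the deletions and 17 (without gpr1 array 2) to 142 (without wild-type array 1) in the mean. The lone array left in a group is assumed to vary like those of the other groups. The correlation of the deletions ranged from 0.573 (without gpr1 array 2) to 0.844 (without wild-type array 1).

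Lists past the threshold numbered 12, 10, 3 and 11. With an estimated correlation 0 passed in all 4 by camera (3, 4, 2 and 4 at an unadjusted p under 0.05). Fry gave 0, 4, 0 and 0 by direction (7, 10, 2 and 11 at an unadjusted p under 0.05) and 6, 13, 1 and 10 in either direction. On the values as deposited 7, 8, 5 and 7 passed. Leaving out an array gave 4 (without wild-type array 1) to 12 in the gpr1 deletion and 7 (without wild-type array 1) to 12 in the mean.

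The log2 change of GPR1 in the gpa2 deletion, 0.12 and not past the threshold, was -0.91 on the values as deposited and ranged from -0.0815 without wild-type array 1 to 0.33 without wild-type array 2. Of 66 results for named genes, 61 kept their direction and side of the threshold under median centring, 66 without a floor, 60 with the block (the other 6 passed there alone, among them FMP33 and HSP26 in the gpr1 deletion), 37 without the filter, 48 without a trend, 27 unmoderated and 51 as deposited. Probe sets near the floor are limited by signal over background: a deleted or silent gene gives only a lower bound on its change.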

Other observations

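Of the tests in this part, those on chromosome neighbours, on brightness of the shared genes and on ribosomal RNA were chosen after the result was seen, and the test with separate wild-type arrays replaced an earlier one.

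Cell wall, nitrogen and filamentous growth genes held single members past the threshold in the gpa2 deletion while their lists were not called. CCW12 was the member of the cell wall list past the threshold in the gpa2 deletion, where the list's median was 0.04 (0.03 in the gpr1 deletion, with none passing by limma and 4 lower at an unadjusted p under 0.05). PUT4, the proline permease, rose in the gpa2 deletion while the nitrogen list had medians of -0.02 and -0.02. DIA1, a gene of invasive growth, fell there (log2 change -1.19, adjusted p = 0.0486), with medians of -0.01 and -0.17 for the filamentous growth list in the gpr1 and gpa2 deletions. In the mating list (medians 0.05 and 0.03) none passed by limma, with 3 higher and 3 lower, and 3 higher and 2 lower, at an unadjusted p under 0.05; the a-factor transporter gene STE6 read 1.14 and 0.87, and PRM5 -1.13 and -0.95. None of these lists was called by camera (adjusted p of 0.411 or more).

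The other lists not called in either deletion are given as medians in the gpr1 and gpa2 deletions. They were ribosomal proteins (0.00 and 0.02, with a mean of 0.14 and 0.23), heat shock chaperones (0.09 and 0.14), glycolysis (-0.06 and -0.11), sulfur (-0.13 and -0.13), purine (-0.08 and -0.14), ergosterol (-0.07 and -0.06), seripauperins (-0.01 and 0.05), meiosis (0.06 and 0.20), the proteasome (0.04 and 0.02) and housekeeping genes (-0.07 and 0.06). The glycolysis mean was positive (0.12 and 0.34) because of TDH3 (4.98 and 10.66, SE 2.43, adjusted p = 0.818 and 0.115), read by a shared probe set at the floor on both wild-type arrays and on gpr1 array 1. Mitotic genes (0.11) and iron and copper genes (0.01) were not called in the gpa2 deletion. Histones (0.28 and 0.20) and alpha-cell markers (-0.40 and -0.17) had 4 measured members each and were not tested as lists.

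Probe sets that moved in both deletions included chromosome neighbours in the R64 gene order, PRM7 with BSC1 and AQY2 with YLL053C. Whether each pair reads 1 transcript or 2 in this background was not tested, and the count below takes each pair as 2 genes. The labels do not say whether both mutants come from 1 strain. A local difference between the wild type and both mutants may lie behind these pairs. Among 49 genes, 47 past the threshold in the mean of both deletions and 2 at the floor on all arrays of 1 side, there were 2 neighbouring pairs, and a share of 0.068 of 10000 random sets held as many (0.422 on average), which leaves this open; among called genes alone, the version written first, there was 1 pair and the share was 0.334, which would have counted against it. Wild-type arrays shared by both comparisons stay open too: with a separate wild-type array for each deletion the smaller covariance was 0.0788. The earlier test, a covariance of 0.212 against a simulated maximum of 0.0699, would have counted against this. Its simulation gave wild type no more spread than the mutants and drew probe sets independently. For the 12 probe sets called in both, the median ratio of their change with and without brightness as a covariate was 1.01 (SE 0.0305 over probe sets). The covariate draws on differences between the 2 arrays of a group, and calls favour probe sets where those are small. A ratio near 1 was therefore likely beforehand, and brightness stays open for these and for the other probe sets. An earlier version used gpr1 array 1 alone. No biological explanation was tested.

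Of the mitochondrially encoded transcripts, OLI1 fell by 9.20 and COX1, on its brightest probe set, fell by 5.25 on the log2 scale from wild-type array 1 to wild-type array 2. Another, dimmer probe set of COX1 differed by 0.05 and AI4 by 0.41, while ATP6 read -2.24 and COX3 -2.47. These genes, like CIT2, DLD3 and the others below, were chosen after their values were seen. Only 2 of 28 mitochondrial probe sets were bright enough to judge. These 28 leave out 3982_at, which names no gene and by its number stands between probe sets of SCEI and COX2. It lay at the floor on both wild-type arrays, so it cannot show a fall between them, and whether it is mitochondrial was not tested. Loss of mitochondrial DNA may be the source of the falls in OLI1 and COX1 and stays open: DLD3 read -1.22 and CIT2 -0.58, genes that rise in cells without it. Other genes looked at with them read higher, PDR15 by 0.76, CIT1 by 0.69, IDH2 by 0.47, PDR5 by 0.17, ACO1 by 0.16 and IDH1 by 0.08. Under a bound with a sign, used before it was corrected to the bound as written, loss of mitochondrial DNA would have been excluded. RNA degradation alike across all transcripts is argued against as the whole source, since 0% of 865 nuclear probe sets of similar level fell as far (largest fall -2.55). The ratio of the 3' to the 5' control of SPT15 was 10.3 on wild-type array 2 against 3.16 to 4.83 on the others, so lower RNA quality there may add to it. That of ACT1 was 1.29 on wild-type array 2, 1.26 on wild-type array 1 and 1.35 to 1.54 on the 4 mutant arrays. Loss of RNA without poly(A) is argued against as the whole source by the 10 ribosomal RNA controls. All read lower on wild-type array 2, by -0.59 to -2.22 with a median of -1.43, far less than OLI1. Another ribosomal RNA probe set, RDN18-1, read lower on array 2 in every group. Its log2 intensities were 11.27 and 9.14 in wild type, 10.52 and 8.97 in the gpr1 deletion, and 11.06 and 9.54 in the gpa2 deletion. OLI1 stayed bright on those mutant arrays (12.49 and 12.13, and 12.11 and 11.15), so whether such a loss adds to the falls is open. No biological explanation was tested.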
